A study of Arabidopsis thaliana with 63 samples.

How the data were processed

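The 3′ ends of microRNA precursors (pre-miRNAs) were read by 3′ RACE-seq in 63 Arabidopsis seedling libraries of 29 genotype groups. Per the labels' protocols, RNA of 40 to 400 nt was taken from total RNA of 14-day-old seedlings. A 3′ adaptor was ligated to it with truncated T4 RNA ligase 2, and products of 60 to 420 nt were kept for reverse transcription. PCR with forward primers specific to each pre-miRNA ran for 10 cycles and a second PCR for 16 cycles, and products of 150 to 230 bp were sequenced. The sample labels give an age of 3 weeks, which disagrees with the protocol. No molecular identifiers are described, so reads are not independent molecules and every interval below covers counting error only.

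Per the submitters' processing notes, the reads were handled with Trim Galore and HISAT2. Their versions and the genome build are not given in the sources used here. Each deposited file lists reads placed within 50 nt of a hairpin, with a signed whole-number read count as the authors deposited it. What the sign means is not stated in the files. Positively signed reads were used, and the negatively signed ones served as an alternative. The files list 227 loci, and 204 hairpin windows matched the TAIR10.1 reference exactly. Coordinates below are from that match. MIR5642a and MIR5642b, 2 hairpins within ribosomal DNA, were left out of all tail measures.

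Each read was compared with its hairpin (match 1, mismatch penalty 3, minimum score 15) and kept when at least 30 nt were templated. Bases after the last templated position, up to 10 nt, were the tail. Reads with 1 mismatch near the end were kept as untailed and made up 0.75 to 3.44% of reads. This held only where the bases from the mismatch on were not all alike and the last one matched the template. A mismatch at the last base itself was counted as a tail of 1 nt. Longer tails or tails with an unread base made up 0.0338 to 4.36% and were left out. A read scoring equally at more than 1 locus was dropped, which removed 12.3% of reads at MIR169l, 5.24% at MIR169n and 0.129% at MIR169j. A U tail was made only of U, a C tail only of C. A tail that begins with the next template base cannot be told from genomic sequence, and is counted as untailed sequence ending further downstream. The intact end of a pre-miRNA was its commonest untailed 3′ end over the Col-0 libraries, weighted equally. It need not be the Dicer product of the mature annotation. A read, tailed or not, counted as intact when its templated part stopped there.

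The caller was tested on 20000 simulated reads and returned the right class for 96.4% of the 15718 visible tails and untailed ends. It returned 0% of tails hidden by the template. On simulated data the per-pre-miRNA test recovered 21.7, 61.8 and 63.5% of U-tail changes of 1, 2 and 3 log2 units in heso1-1, with 3.96% false calls. For intact ends in dcl1-7 the shares were 40.3, 65.6 and 88.3%, with 2.92% false calls. For C tails in ntp6-1ntp7-1 they were 36.5, 86.2 and 94.4%, with 3.92% false calls. The simulated spread was drawn separately for each pre-miRNA and library, without shifts shared by a whole library. These shares therefore do not cover calls that such shifts could cause.

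Positive reads per library ranged from 1317290 to 37985814. Most were products with too little templated sequence (68.4 to 99% of reads, median 95.8%). Reads assigned to pre-miRNAs ranged from 12624 to 982385 per library (median 145484, 12519849 in all). Between 27 and 95 pre-miRNAs had at least 50 reads in a library, and 19 had them in every library. Over 60 replicate pairs the chi-square per degree of freedom was at least 9.5 (median 74.4), so no pair of libraries differed by as little as sampling noise. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

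The value of a library was the unweighted mean, over pre-miRNAs with at least 50 reads in every library compared, of the share of reads in a class. Group means of these values were compared by two-sided exact permutation tests, giving every pre-miRNA equal weight. Benjamini-Hochberg adjustment ran over the 3 intact-end and over the 5 tailed-share comparisons. The spread among Col-0 and the nucleotidyl transferase genotypes was tested with 100000 shuffles. Single pre-miRNAs were tested with limma 3.58.1 in R 4.3.3 on log2((class reads + 0.5)/(other reads + 0.5)), with at least 50 reads per value and adjusted p under 0.05. A single fit held the 51 libraries of the 19 Columbia groups with at least 2 libraries. Fold changes below are differences of these log2 odds, and depend on the pseudocount where the class has few reads, so that a value can differ from 0 with no such read in either group. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

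The groups, tests, lists and the rule for named pre-miRNAs were fixed before the data were examined. The rule takes up to 12 falls and 12 rises with the largest change per limma comparison. It adds the first measured locus of MIR156, MIR159, MIR164, MIR166, MIR167, MIR168, MIR171, MIR172, MIR319, MIR390, MIR393, MIR396, MIR398 and MIR408, and the extremes in Col-0 (10 for U, 10 for C, 5 at each side for intact ends). The 9 lists held families with the guide on the 3′ arm, families with the guide on the 5′ arm, loop-to-base families with a long stem, loop-to-base families with a short stem, nutrient-responsive families, auxin and organ boundary families, growth and phase change families, families conserved in flowering plants, and pathway feedback families. Each list was compared with the other tested pre-miRNAs by Fisher's exact test, adjusted over the 9 lists. A further 43 comparisons of library values lay outside that design and were adjusted together. None of them reached an adjusted p of 0.05, the smallest being 0.0853. Another 24 tests by position of the end, also outside the design, were adjusted among themselves.

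Several steps were added after the data had been seen. They are the limma comparisons of U tails for the HESO1 transgene and for ago1-36, the tests with the set letter as a block, the tests by last templated base, the use of negatively signed reads, and other reference ends. limma was also run on other tail classes, intact ends and genotypes outside the design. Of these only MIR169m C tails in ago1-36 and transgene U tails against Col-0 were looked at further. Counts of intact-end calls from these runs are given beside those of hyl1-2. The intact-end and tailed-share alternatives are judged by adjusted p, as the design states. They were first judged by unadjusted p, and this was corrected after the first table had been seen. The design stated that the transgene comparison could not fall under 0.05. With 28 splits of 2 against 6 libraries the smallest two-sided p is in fact 0.0357.

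Sample descriptions give a sequencing lane for every library but Col-0 replicates 1 to 3, and a set letter, a or b, for the nucleotidyl transferase mutants and heso1-1 replicates 4 and 5. Col-0 replicates 4 and 5 were placed in sets a and b because they share these replicate numbers. heso1-1 was read in lanes 5 and 6, dcl1-7 in lane 8 and the Col-0 libraries with a lane in lanes 1, 2 and 4, so no lane given held both Col-0 and heso1-1 or dcl1-7. Libraries of other genotypes read in the lanes of heso1-1, dcl1-7, se-1 and hyl1-2 are compared with these over the 19 pre-miRNAs common to all libraries, leaving out other heso1 genotypes for heso1-1 and the other cutting mutants for the rest. heso1-2 and Ler shared lane 3. Only lane numbers were recorded here, not sequencing runs, so libraries with the same lane number may come from different runs. The lane comparisons below assume that they do not. heso1-1 replicate 6, of lane 5, had 139946 reads at loci other than MIR hairpins. heso1-1 replicate 4, also of lane 5, had 77, and Col-0 replicate 6, of lane 4, had 214056. Same-numbered libraries deviated together only for ago1-36 and Col-0 (correlation over 43 pre-miRNAs 0.252 to 0.489 in 3 pairs), so that comparison is also given with the replicate number as a block. The knocked-out genes themselves were not measured by this assay, so the genotype labels could be checked only through the tails.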

Results

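3′ RACE-seq reads the last bases of each pre-miRNA, including bases added after transcription. It was applied to seedlings of 29 genotypes. Col-0, the Columbia wild type, and heso1-1, a mutant of the terminal uridylyl transferase HESO1, had 6 libraries each. Ler (the Landsberg erecta wild type), dcl1-7, se-1, hyl1-2, ago1-36 and hen1-8 had 3 each. There were 2 libraries each of 11 nucleotidyl transferase genotypes and of heso1-1 carrying a HESO1 transgene. Another 9 genotypes had 1 library and therefore no replicate check. Between 12624 and 982385 reads per library lay on pre-miRNAs.

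In Col-0 both C and U were added to most measured pre-miRNAs, and C more often than U. Across 89 pre-miRNAs the median share of reads was 10.9% for C tails, 6.38% for U tails, 0.506% for A tails and 0.0646% for G tails. C exceeded U in 60 pre-miRNAs and U exceeded C in 29. MIR160c, whose miRNA targets auxin response factors, had the highest C-tail share at 43.8% ± 5.77 (SD, n = 6). It was followed by MIR161 (37.5%), MIR156c (35.2%), MIR156f (32.4%), MIR319b (31.5%), MIR171b (31.5%), MIR157a (31.4%), MIR447b (30.6%), MIR167b (28.9%) and MIR156d (28.8%). MIR164c, whose miRNA targets NAC genes of organ boundaries, had the highest U-tail share at 38.6% ± 11.4 (SD, n = 6). MIR830 (33.7%), MIR166c (32.7%), MIR172a (30.8%), MIR157c (29.5%), MIR400 (28.8%), MIR164a (25.9%), MIR172b (23.8%), MIR171c (22.8%) and MIR169i (22.5%) came next. Tails were short: 84.0% ± 2.21 (SD, n = 6) of tailed Col-0 reads carried 1 nt. Of tailed reads, 52.8% ± 5.83 held only C and 36.1% ± 6.06 only U.

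These loci are given here as positions on TAIR10.1. MIR160c lies on chromosome 5 from 19009094 to 19009182 on the minus strand, and MIR164c on chromosome 5 from 9852674 to 9852775 on the plus strand. MIR161 lies on chromosome 1 from 17825685 to 17825857 (plus). MIR165a, on chromosome 1 from 78927 to 79037 (minus), overlaps AT1G08765 on the other strand. MIR400 lies within AT1G32583 on chromosome 1 from 11785936 to 11786037 (plus). MIR396b is on chromosome 5 from 13611798 to 13611932 (plus), MIR390a on chromosome 2 from 16061954 to 16062060 (plus) and MIR396a on chromosome 2 from 4142323 to 4142473 (minus). A C follows the intact end of MIR165a in the genome, so a C tail there cannot be seen. Its measured C share of 0.0319% beside a U share of 20.04% is bounded by this.

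The intact 3′ end accounted for a median of 42.8% of reads in Col-0. It was most frequent in MIR160c (90.3%), MIR164c (89.7%), MIR166f (87.0%), MIR159a (86.4%) and MIR399b (84.8%). It was least frequent in MIR397b (6.7%), MIR173 (12.5%), MIR447b (12.6%), MIR447a (15.7%) and MIR172a (17.2%). Among 72 pre-miRNAs with an annotated 3′ arm small RNA, the commonest end matched the annotated end in 19 and lay within 2 nt in 29. In 12 it lay 20 to 22 nt upstream.

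The heso1-1 comparison asks which tails depend on HESO1. U tails fell in heso1-1 from 8.57% ± 1.12 to 1.65% ± 0.376 of reads (SD, n = 6 each, 37 pre-miRNAs), a ratio of 0.193. All 6 heso1-1 libraries lay below every Col-0 library (exact permutation test, p = 0.00216, the smallest that 924 splits allow). In MIR160c U tails fell from 21.2% ± 4.08 to 0.808% ± 0.31, a log2 odds change of −5.08 ± 0.26 (SE, limma adjusted p = 7.22e-19), with 6 of 6 libraries below every Col-0 library. In MIR165a, whose miRNA targets class III HD-ZIP genes, they fell from 20.04% to 0.996% (log2 −4.65). MIR157c (−5.92), MIR830 (−5.88), MIR159b (−5.78), MIR166c (−5.35), MIR161 (−5.06), MIR393b (−5.03), MIR395a (−4.82), MIR172a (−4.61), MIR169i (−4.60) and MIR166a (−4.47) fell by similar log2 amounts.

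Of 83 pre-miRNAs tested with limma, 49 had lower and 0 had higher U-tail odds in heso1-1, against 53 at an unadjusted p under 0.05. Among the first loci of the fixed families, MIR393a (−4.08), MIR390a (−4.08), MIR398a (−3.96), MIR164a (−2.75), MIR167a (−2.12) and MIR168a (−1.48) also fell. MIR396a (−1.22), MIR159a (1.29), MIR171a (1.41) and MIR408 (1.65) did not pass the test. MIR156b and MIR319a had too few reads to be tested, and neither the first tested MIR156 locus, MIR156c (−1.51), nor the first tested MIR319 locus, MIR319c (1.61, with 0% in both groups), passed. MIR408 held 0 U-tailed reads of 1076 in Col-0, which allows a share of up to 0.279% over the group. U tails were a small part of heso1-1 tails: 6.59% of tailed reads held only U and 83.6% only C. When only tails of at least 2 nt were counted 19 pre-miRNAs fell. Over those whose next template base is A or G 13 fell, since fewer were tested.

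**Figure D1:**
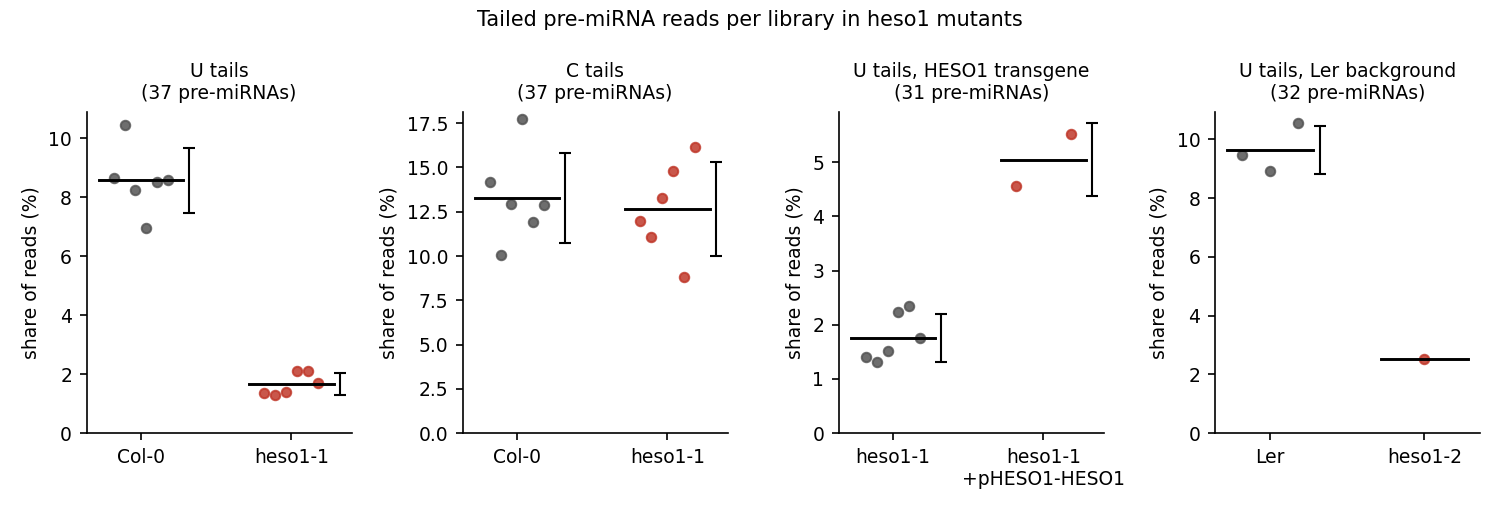
Each point is the mean share of reads (%) with the named tail in 1 library, for heso1-1 against Col-0, the HESO1 transgene against heso1-1, and heso1-2 against Ler; black lines are means and error bars SD. U-tail values of all 6 heso1-1 libraries (mean 1.65%) lie under those of all 6 Col-0 libraries (mean 8.57%), while C-tail values overlap.

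By list, U tails fell in 22 of 32 measured pre-miRNAs with the guide on the 3′ arm (22 adjusted over the list alone) and in 20 of 33 with the guide on the 5′ arm (20 adjusted over the list alone). Of the auxin and organ boundary families 9 of 11 fell (9 adjusted over the list alone), among them MIR160c, MIR164a and MIR393b. Of the growth and phase change families 17 of 25 fell (17 adjusted over the list alone), among them MIR157c, MIR172a and MIR166a. Of the nutrient-responsive families 11 of 19 fell (11 adjusted over the list alone), with MIR395a and MIR398a as examples, and of the conserved families 41 of 63 (41 adjusted over the list alone). In the pathway feedback list, precursors whose miRNAs target DCL1, AGO1 or AGO2, 3 of 5 fell (3 adjusted over the list alone). In the loop-to-base lists 2 of 6 with a short stem and 1 of 3 with a long stem fell (2 and 1 adjusted over the list alone). No list differed from the other pre-miRNAs (Fisher's exact test, smallest adjusted p = 0.498).

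**Figure D2:**
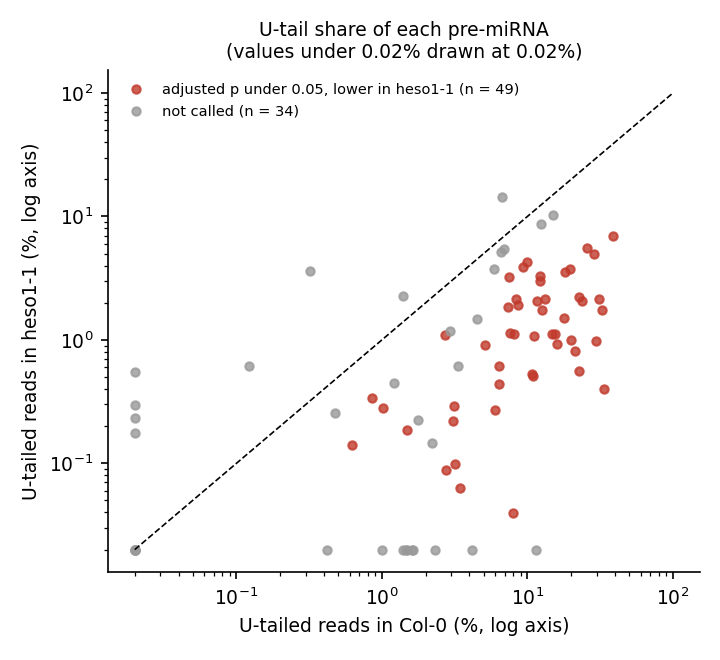
Each point is 1 of 83 pre-miRNAs, with the mean U-tail share (%) in Col-0 on the horizontal and in heso1-1 on the vertical log axis; values under 0.02% are drawn at 0.02% and the dashed line marks equal shares. The 49 red points passed the test and all lie under the line.

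C tails of all lengths together did not pass the test in heso1-1. They stood at 12.7% ± 2.66 against 13.3% ± 2.56 in Col-0 (SD, n = 6 each), a difference smaller than the spread between libraries (exact permutation p = 0.71). C tails of at least 2 nt alone fell, by 0.431 percentage points (exact permutation p = 0.013). In single pre-miRNAs limma gave 7 falls and 0 rises of 83 (16 at an unadjusted p under 0.05). They were MIR399a (−2.77, 18.3 to 3.83%), MIR822 (−2.59), MIR165b (−2.36, 12.0 to 2.82%), MIR171a (−2.20, 10.2 to 2.82%), MIR167a (−2.14, 7.45 to 1.88%), MIR164c (−1.99, 15.4 to 3.92%) and MIR169h (−0.91, 19.6 to 12.1%). Of the first loci of the fixed families, MIR164a (−1.01), MIR396a (−1.08), MIR168a (−0.51), MIR166a (−0.37), MIR159a (−0.12), MIR393a (−0.11), MIR172a (−0.02), MIR398a (0.19), MIR408 (0.67) and MIR390a (0.93) did not pass. A fit on the 2 groups alone gave 4, without the call of MIR399a, MIR822, MIR164c and MIR169h, depth weights gave 16, and leaving out heso1-1 replicate 1 gave 3. Weighted by reads, the mean difference turned to 2.79 percentage points, by the median over pre-miRNAs to 0.205 and without Col-0 replicate 4 to 0.288. By list, C tails fell in 3 of 33 pre-miRNAs with the guide on the 5′ arm (5 adjusted over the list alone) and in 6 of 63 of the conserved list (6 adjusted over the list alone), and no list differed from the others (Fisher's exact test, adjusted p = 1).

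heso1-1 plants carrying a HESO1 transgene had more U tails than heso1-1. The share was 5.04% ± 0.673 (SD, n = 2) against 1.76% ± 0.438 (SD, n = 6) over 31 pre-miRNAs. Both libraries lay above every heso1-1 library (exact permutation p = 0.0357, the smallest for 28 splits). Among the 7 libraries with the same lane number the values were 4.57 and 5.52% against 1.31 to 2.23%. In limma, run after this was seen, U tails rose in 20 and fell in 0 of 38 pre-miRNAs (22 at an unadjusted p under 0.05; 12 rose without transgene replicate 2). In MIR160c they rose from 0.808 to 9.2% (log2 3.70), in MIR166a from 0.534 to 5.05% (3.34), in MIR165a from 0.996 to 7.41% (2.97) and in MIR398c from 1.76 to 11.7% (2.89). MIR159b (4.27), MIR157c (3.46) and MIR169m (2.75) rose too. The transgene plants remained under Col-0, at 4.91% ± 0.716 against 8.66% ± 0.956 (34 pre-miRNAs, 2 of 2 below). That comparison lay outside the design (exact permutation p = 0.0357, adjusted p = 0.171).

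In the Ler background the single heso1-2 library had a mean U-tail share of 2.53% against 9.64% ± 0.822 in Ler (SD, n = 3), over 32 pre-miRNAs and in the same lane. Its pooled share was 1.11% (95% Wilson interval 1.05 to 1.18%, 88989 reads), and that of Ler 4.00% ± 0.936 (SD, n = 3). C tails stood at 8.53% against 9.63% ± 1.10. With 1 library no test was made. The heso1-1se-1 library, a double mutant, had 3.81% U tails against 9.25% ± 1.28 in Col-0 (n = 6, 26 pre-miRNAs), with a pooled share of 3.08% (Wilson 2.78 to 3.41%). Its mean C-tail share was 15.4% against 13.1% ± 2.08. Its pooled C-tail share was 22.2% (Wilson 21.5 to 23.0%), above the Col-0 range of 10.6 to 15.6%. Its intact ends stood at 39.7% against 49.6% ± 3.64.

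DCL1, SERRATE (SE) and HYL1 act in cutting the precursors, and their mutants were compared with Col-0 for the position of the 3′ end. In dcl1-7 the intact end fell to 39.1% ± 0.458 of reads from 48.7% ± 2.59 (50 pre-miRNAs). In se-1 it fell to 35.0% ± 1.05 from 47.4% ± 3.49 (39 pre-miRNAs) and in hyl1-2 to 41.3% ± 0.884 from 48.5% ± 2.43 (45 pre-miRNAs; SD, n = 3 and 6 throughout). The differences were −9.59, −12.4 and −7.18 percentage points. In each mutant all 3 libraries lay below every Col-0 library (exact permutation p = 0.0119, adjusted p = 0.0119 over 3 comparisons, the smallest that 84 splits allow). Lane 2 is given for the 3 hyl1-2 libraries (40.4, 41.3 and 42.2%) and 1 Col-0 library (43.9%). It is also given for 1 se-1 library (34.5%), beside that Col-0 library at 40.8% on the se-1 set. Over the 19 pre-miRNAs common to all libraries that order turned for hyl1-2, with the Col-0 library at 43.6% and hyl1-2 at 44.4 to 46.4%, while the se-1 library stood at 39.5%. Weighted by reads, hyl1-2 changed sign (7.01 percentage points), and the se-1 difference (−11.7) no longer passed. With untailed reads alone the hyl1-2 difference (−5.08) did not pass either.

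In dcl1-7, 20 pre-miRNAs had lower and 2 had higher odds of an intact end of 67 tested with limma (27 at an unadjusted p under 0.05). MIR396a, whose miRNA targets growth-regulating factors, fell from 50.6 to 8.9% (−3.81 ± 0.64 SE, adjusted p = 2.71e-05, 3 of 3 libraries below). MIR400 fell from 49.1 to 4.45% (−4.99), MIR390a from 34.3 to 1.74% (−4.72), MIR170 from 57.9 to 7.63% (−4.38), MIR398c from 67.6 to 17.4% (−3.46), MIR157a from 53.9 to 11.7% (−3.29), MIR172b from 42.8 to 7.05% (−3.25) and MIR162a from 60.9 to 17.1% (−3.18). MIR166e (−4.74), MIR160a (−4.02), MIR398b (−2.74), MIR393a (−1.79) and MIR171a (−1.65) fell as well. MIR319b held 0 intact reads of 398 in dcl1-7, which allows up to 0.754% over the group, against 17.5% ± 2.48 in Col-0 (SD, n = 2). MIR396b rose from 34.8 to 81.3% (3.16) and MIR161, whose miRNA targets pentatricopeptide repeat genes, from 36.0 to 53.8% (1.06). MIR166a (59.5 and 53.5%), MIR168a (78.04 and 74.9%) and MIR164a (84.0 and 90.9%) did not pass the test, nor did MIR167a (39.3 and 25.4%), MIR172a (17.2 and 7.91%) and MIR398a (42.2 and 41.6%). With at least 200 reads per value 12 pre-miRNAs passed.

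In se-1, 26 pre-miRNAs fell and 0 rose of 56 (27 at an unadjusted p under 0.05). MIR164a fell from 84.0 to 27.0% (−4.09), MIR403, whose miRNA targets AGO2, from 36.2 to 1.45% (−4.44), MIR396a from 50.6 to 10.6% (−3.94) and MIR390a from 34.3 to 6.19% (−3.85). MIR169f fell from 34.1 to 3.92% (−3.58), MIR164c from 89.7 to 52.2% (−3.57), MIR398a from 42.2 to 8.9% (−2.94) and MIR158a from 54.1 to 16.8% (−2.55). MIR160a (−4.92), MIR166e (−4.56), MIR173 (−3.82), MIR171a (−2.46), MIR167a (−2.19) and MIR168a (−1.21) fell too. MIR162b held 0 intact reads of 346, which allows up to 0.867%, against 19.0% ± 13.2 in Col-0 (SD, n = 5). MIR166a (59.5 and 64.1%) and MIR172a (17.2 and 5.05%) did not pass. Counts were 12 with at least 200 reads per value, 14 with depth weights and 11 at the annotated end.

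In hyl1-2, 13 fell and 0 rose of 63 (20 at an unadjusted p under 0.05). MIR157a fell from 53.9 to 6.6% (−4.07), MIR390a from 34.3 to 3.05% (−4.06), MIR162a from 60.9 to 12.2% (−3.57), MIR166f from 87.0 to 45.3% (−2.95), MIR393b from 47.9 to 16.0% (−2.26), MIR396a from 50.6 to 17.6% (−2.25) and MIR161 from 36.0 to 18.8% (−1.31). MIR403 (−4.64), MIR163 (−1.82), MIR844 (−1.45) and MIR390b (−1.22) fell as well. MIR319a held 0 intact reads of 272, which allows up to 1.1%, against 33.8% ± 38.5 in Col-0 (SD, n = 2), so the Col-0 value is poorly known. MIR164a (84.0 and 85.2%), MIR166a (59.5 and 63.9%), MIR167a (39.3 and 31.9%), MIR168a (78.04 and 71.2%), MIR171a (48.2 and 31.6%), MIR172a (17.2 and 6.64%) and MIR398a (42.2 and 33.5%) did not pass. With at least 200 reads per value 6 passed, at the annotated end 4, and without hyl1-2 replicate 2 also 6. These 3 comparisons share the Col-0 libraries, and no overlap between them was tested. Outside the design, limma called intact ends in 10 of 57 for ntp9-1 (10 fell), 10 of 52 for ago1-36 (8 fell) and 9 of 56 for ntp2-1 (8 fell). For ntp4-1 (45 tested) and ntp6-1 (50 tested) it called 0. A count near that of hyl1-2 is therefore not particular to the cutting mutants.

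**Figure D3:**
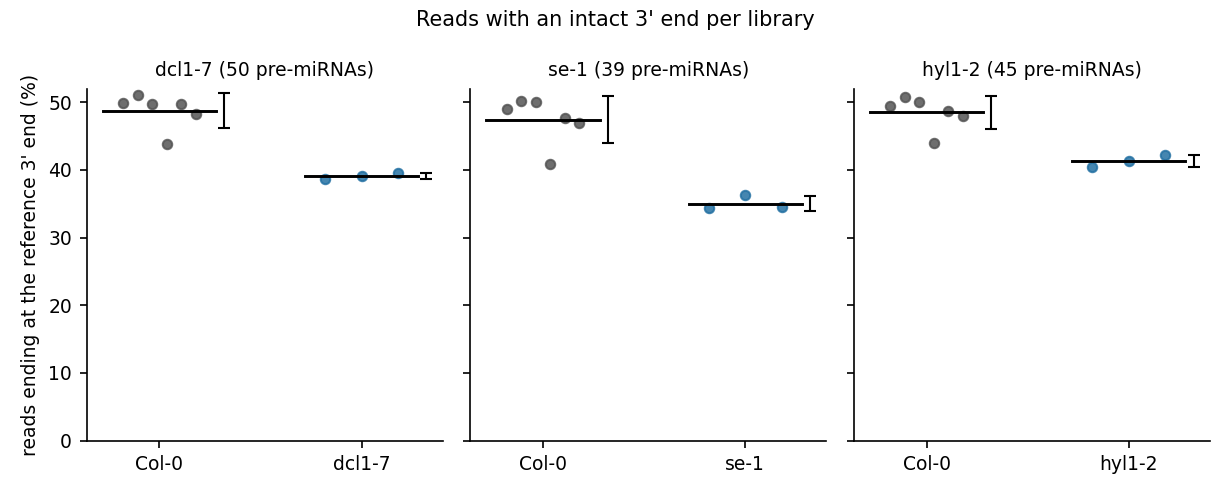
Each point is the mean share of reads (%) that end at the intact 3′ end in 1 library, for Col-0 and dcl1-7, se-1 or hyl1-2; black lines are means and error bars SD. All 3 libraries of each mutant lie under all 6 Col-0 libraries, at means of 39.1, 35.0 and 41.3%.

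Ends downstream of the intact end made up 28.9% of reads in dcl1-7 against 22.3% in Col-0, 30.1 against 23.8% for se-1 and 27.8 against 22.0% for hyl1-2. Each difference had an exact permutation p of 0.0119 with 3 libraries per mutant (adjusted p = 0.0476 over 24 tests made outside the design). Ends upstream did not pass the adjustment. They made up 34.9 against 28.8% for se-1 (exact permutation p = 0.0238, adjusted p = 0.0714), 32.0 against 29.0% for dcl1-7 (exact p = 0.0595, adjusted p = 0.143) and 30.9 against 29.6% for hyl1-2 (exact p = 0.262, adjusted p = 0.393). In hen1-8 downstream ends made up 27.7 against 22.0% (exact permutation p = 0.0357, adjusted p = 0.0952).

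By list, intact ends changed in 9 of 28, 8 of 22 and 4 of 28 pre-miRNAs with the guide on the 3′ arm in dcl1-7, se-1 and hyl1-2 in turn (9, 8 and 4 adjusted over the list alone). With the guide on the 5′ arm they changed in 8 of 29, 15 of 26 and 5 of 26 (8, 15 and 5 adjusted over the list alone). In the auxin and organ boundary list 3 of 10, 7 of 9 and 3 of 9 fell (3, 7 and 4 adjusted over the list alone), MIR390a in each mutant and MIR164a and MIR164c in se-1. In the growth and phase change list 7 of 23, 4 of 18 and 4 of 24 changed (7, 4 and 4 adjusted over the list alone), in the nutrient-responsive list 3 of 14, 5 of 13 and 0 of 12 (3, 5 and 0 adjusted over the list alone). In the conserved list 16 of 55, 21 of 46 and 9 of 52 changed (16, 21 and 9 adjusted over the list alone). In the pathway feedback list 2 of 5, 4 of 4 and 2 of 5 fell (2, 4 and 2 adjusted over the list alone), with MIR162a in dcl1-7 and hyl1-2 and MIR403, MIR162b, MIR168a and MIR168b in se-1. Short-stem loop-to-base precursors fell in 2 of 6, 3 of 5 and 1 of 6 (2, 3 and 2 adjusted over the list alone) and long-stem ones in 1 of 2, 0 of 2 and 1 of 4 (1, 0 and 1 adjusted over the list alone). Fisher's exact test separated no list from the other pre-miRNAs after adjustment. The smallest adjusted p was 0.183 in se-1, for pathway feedback and for growth and phase change, 0.515 in hyl1-2 and 1 in dcl1-7.

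Tailed reads were compared in the same mutants and in ago1-36 and hen1-8, mutants of the miRNA effector AGO1 and the small RNA methyltransferase HEN1. ago1-36 had 31.4% ± 1.16 tailed reads against 27.1% ± 2.41 in Col-0 (39 pre-miRNAs), with 2 of 3 libraries above every Col-0 library (exact permutation p = 0.0357, adjusted p = 0.139). Differences were 3.69 percentage points in hyl1-2 (exact permutation p = 0.0595, adjusted p = 0.139), 2.55 in dcl1-7 (exact permutation p = 0.0833, adjusted p = 0.139), 1.74 in se-1 (exact permutation p = 0.286, adjusted p = 0.357) and −0.116 in hen1-8 (exact permutation p = 0.952, adjusted p = 0.952). None passed the adjustment over the 5 comparisons. Same-numbered ago1-36 and Col-0 libraries deviated together, and with the replicate number as a block the ago1-36 difference was 5.42 over 3 pairs (exact p = 0.25, the smallest for 3 pairs). Weighted by reads, dcl1-7 (7.14), hyl1-2 (10.8) and ago1-36 (9.56) passed, and se-1 (−1.09) and hen1-8 (11.9) changed sign.

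The nucleotidyl transferase mutants ask which enzyme adds the C and whether other enzymes add U. Their labels name no heso1 allele, so they cannot show which enzyme adds the U left in heso1-1. The double mutant ntp6-1ntp7-1 and the triple mutant ntp2-1ntp6-1ntp7-1 had the lowest C-tail shares, 8.9% ± 2.19 and 8.90% ± 2.79 (SD, n = 2 each), against 13.5% ± 2.39 in Col-0 (n = 6, 30 pre-miRNAs). ntp7-1 alone stood at 9.93%, ntp10-1 at 11.1% and ntp5-1 at 15.9%. The spread of C among the 12 genotypes (SD 2.34) did not pass (permutation p = 0.112), but did with at least 200 reads (2.56) or pooled reads (2.68). U tails differed among genotypes (SD 1.73, permutation p = 0.00153), though not with at least 200 reads (1.33), pooled reads (1.06) or tails of at least 2 nt (0.179). They stood at 6.66% in ntp2-1, 6.76% in ntp5-1, 7.25% in ntp9-1 and 7.74% in urt1-1, a mutant of the uridylyl transferase URT1, and at 11.8% ± 0.661 in the double and 11.3% ± 0.586 in the triple mutant, against 9.37% ± 1.01 in Col-0.

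The libraries came in sets a and b, and C tails were higher in set a in 11 of 11 mutant genotypes (14.1 against 10.7%, permutation p = 0.000977 by exact sign flips). U tails were lower in set a in 11 of 11 (8.49 against 9.8%). Within sets, with Col-0 replicates 4 and 5 alone, the spread of C passed (SD 2.43, permutation p = 5e-05 with shuffles within sets), as did that of U (permutation p = 8e-05). The double mutant stood at 10.5 and 7.35% in sets a and b and the triple at 10.9 and 6.92%, against 17.3 and 12.3% in Col-0. The 17.3% of Col-0 replicate 4 was the highest of the 6 Col-0 values. The lowest, 10.2% in replicate 2, lay under the set a libraries of both mutants. In lane 1 alone, Col-0 stood at 12.3% and the double and triple at 7.35 and 6.92%. In lane 2, Col-0 stood at 17.3% and the triple at 10.9%.

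limma, in the fit of 51 libraries, gave 0 calls for C tails in either mutant, with 10 of 54 (double) and 13 of 55 (triple) at an unadjusted p under 0.05. Median changes were −0.73 and −0.72, with 50 of 54 and 49 of 55 pre-miRNAs lower, and the smallest adjusted p was 0.0777 and 0.115. For U tails it gave 0 calls and 1 at an unadjusted p under 0.05 in each. With the set letter as a block, added after the set difference was seen, limma called 12 of 51 in the double and 13 of 51 in the triple, all lower. In the double they included MIR822 (−2.73), MIR169f (−2.07), MIR393a (−2.03), MIR166g (−1.55), MIR166a (−1.38), MIR168b (−1.21) and MIR161 (−0.999). In the triple they included MIR396b (−2.22), MIR393a (−2.03), MIR164c (−1.9998), MIR157c (−1.998), MIR169f (−1.85), MIR164a (−1.82), MIR171b (−1.41) and MIR168b (−0.99). In MIR169f the double mutant had 8.31 and 9.52% C tails in sets a and b. Col-0 replicates 4 and 5 had 34.4 and 24.6%, and all 6 Col-0 libraries a mean of 22.2%. In MIR168b the double mutant had 16.7 and 11.8% against 30.8 and 24.2%, with a mean of 21.8% over all 6 Col-0 libraries.

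No list held a call in these limma comparisons of the double and triple mutant in the joint fit. C-tail counts adjusted over the list alone were 4 in the double for the guide on the 5′ arm, 2 in the double for nutrient-responsive families, 2 in each mutant for auxin and organ boundary, 1 in each for short-stem loop-to-base, and 0 for the others. For U tails they were 0 for every list.

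**Figure D4:**
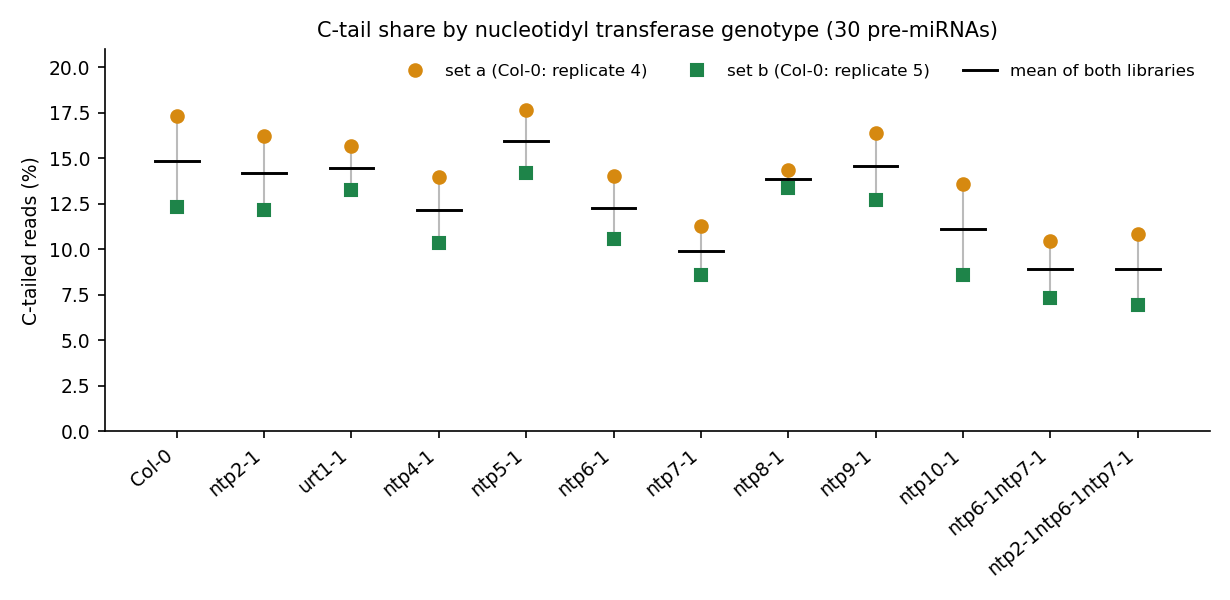
C-tailed reads (% of reads, mean of 30 pre-miRNAs) in Col-0 and 11 nucleotidyl transferase genotypes; circles are set a, squares set b and black lines the mean of both libraries. Set a lies above set b in each genotype, and the double and triple mutant are lowest, with means of 8.9% each.

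The last question was whether tails restore the length of trimmed precursors. Among Col-0 tailed reads whose templated part ended upstream of the intact end, 48.4% ± 3.86 had exactly the intact length with their tail (SD, n = 6, 25 to 42 pre-miRNAs per library). Shuffling tail lengths among those reads gave 44.2% ± 2.71. The difference of 4.20 ± 1.36 percentage points was positive in 6 of 6 libraries (exact sign-flip p = 0.0312, the smallest for 6 libraries). A base error at the last position of an intact read is also scored as a 1 nt tail on an end 1 nt upstream. Such a read has the intact length, and its share in the difference was not tested, so restoration by tailing is not shown.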

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

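The tests of library sets and of sequencing lanes were chosen only after their results had been seen.

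Values that drew attention were a library far from its group and shares in single libraries above every Col-0 library. The 16 tests for a wide gap between libraries covered only Col-0 and heso1-1, over overlapping pre-miRNAs, and 1 showed a gap. They are not independent, so a rate expected by chance does not apply. Col-0 replicate 4 had 40.8% intact ends on the se-1 set, where the nearest other Col-0 library had 46.9%. It was also lowest, without passing, on the dcl1-7 set (43.8%, nearest 48.2%) and the hyl1-2 set (43.9%, nearest 48.0%). Mean U-tail shares lay above every Col-0 library in mac-7 (12.7%), soe1 (12.6%), soe2 (12.9%), tough (13.7%) and prl1prl2 (14.4%). Mean A-tail shares did so in heso1-1se-1 (1.6%), tough (1.46%), cdc5-2 (3.33%) and prl1prl2 (2.08%). Each of these genotypes had 1 library, so none of these differences was tested. The genotypes with high U tails were all read in lane 5, where no Col-0 library with a lane given was read. Pooled over reads, U tails in tough (9.94%, Wilson 9.8 to 10.1%) and prl1prl2 (9.14%) lay within the Col-0 range, and those in soe1 (14.6%, Wilson 14.4 to 14.7%) above it. Reads at the ribosomal hairpins MIR5642a and MIR5642b, outside the tail measures, were above every Col-0 library in 6 libraries, up to 833 per 100 pre-miRNA reads in tough.

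The lower U-tail share in heso1-1 was set against 4 technical explanations. A fault of the positive read class is argued against by the negatively signed reads (−6.58 percentage points), and template bases that hide U by pre-miRNAs followed by A or G (−11.2). For a difference between library sets, 2 of 2 heso1-1 libraries of replicates 4 and 5 lay below both Col-0 libraries of those numbers. No lane given held both genotypes, but in lanes 5 and 6 the lowest library of genotypes without a heso1 allele lay at least 4.36 percentage points above the highest heso1-1 library (6.68 against 2.32% in lane 5), which argues against lane as the whole cause, and loss of HESO1 remains the hypothesis the design names. The real split gave 49 calls and was the only 1 of 100 as large, which argues against a random division of these libraries for the U calls. The highest other gave 40, with Col-0 replicate 5 in place of heso1-1 replicate 5. For the 7 C calls 2 of 100 splits were as large, a share under 0.05, although 1 of them gave 9, more than the real split.

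The lower C-tail share in ntp6-1ntp7-1 and ntp2-1ntp6-1ntp7-1 was set against the library sets and against competition by U tails. Shuffling genotypes only within sets gave a permutation p of 5.0e-05 for the spread of C tails, which argues against the sets as the whole source. With U-tailed reads out of the denominator it was 0.00017, which argues against a shortage of U-free ends. The spread is over all genotypes, so neither test singles out these mutants. Libraries also differed in the share of reads kept with 1 mismatch near the end. It was 1.70 and 0.816% in the double and 1.69 and 0.869% in the triple, against 2.67 and 1.19% in Col-0 replicates 4 and 5. Over the 19 common pre-miRNAs, low mismatch shares stood beside few C tails in other libraries too. They were 0.873 and 9.40% in set b of ntp7-1, and 0.75 and 6.94% in mac-7. High shares stood beside many C tails in set b of ntp5-1 (2.33 and 16.3%) and in hyl1-2 replicate 2 (3.02 and 22.3%). The values did not go together in dcl1-7 replicate 1 (0.895 and 16.1%) or cdc5-2 (2.23 and 11.2%). Whether this library difference bears on C tails was not tested. Loss of a cytidylyl activity may underlie the lower shares and remains a hypothesis found on these data.

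The lower intact share in dcl1-7, se-1 and hyl1-2 was set against the choice of the intact end and the lane. With ends taken from the heso1-1 libraries the differences were −9.38, −10.5 and −6.40 percentage points, and at the annotated end of the 3′ arm small RNA −3.86, −6.40 and −4.33, each past the exact permutation test, which argues against ends fitted to Col-0. The real split gave the most calls for dcl1-7 (22 calls, 1 of 84 splits as large, highest other 20) and se-1 (26 calls, 1 of 84, highest other 20). That is the smallest share that 84 splits allow, and argues against a random division of these libraries. The highest other split put Col-0 replicate 4 in place of dcl1-7 replicate 1, and of se-1 replicate 2. For hyl1-2 (13 calls, 2 of 84, a share under 0.05) the split with Col-0 replicate 4, read in the same lane, in place of hyl1-2 replicate 1 gave 13 too. In lane 8 the libraries of other genotypes, hen1-8 replicate 3 (48.6%) and ago1-27 (50.7%), lay at least 7.56 percentage points above the highest dcl1-7 library (41.1%), which argues against lane as its whole cause. Low intact shares were not particular to the cutting mutants. Over the 19 pre-miRNAs common to all libraries, urt1-1 (43.4 and 42.0%) and ntp9-1 (42.7 and 44.3%) stood near hyl1-2 (44.4 to 46.4%) and se-1 (39.5 to 43.0%). The dcl1-7 libraries (38.7 to 41.1%) lay below them, and ntp6-1ntp7-1 stood higher (52.5 and 51.5%). In lane 5 the lowest other library, ntp9-1 replicate 1, differed from the highest of se-1 by −0.301. The 29 other libraries there spanned 42.7 to 52.7%, against 43.6 to 52.2% in Col-0 and 41.8 and 43.0% in se-1. In lane 2 both others (43.6 and 53.3%) lay above se-1 (39.5%). In lane 5 urt1-1 replicate 1 (43.4%) and ntp5-1 replicate 1 (43.6%) also lay close to the highest se-1 library. The test asked all others to lie above se-1 by more than the range of its libraries, which was not met. Lane therefore stays open for se-1. It also stays open for hyl1-2, where Col-0 replicate 4 differed by −2.78 in lane 2. The direction over pooled reads for hyl1-2 (7.01) and altered cutting, the untested hypothesis of the design, stay open too.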

How the results depend on the processing

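Tests with negatively signed reads, reads with a mismatch left out, other reference ends, set letters, next template base A or G, no MIR169 loci, and all alternatives for the transgene and ago1-36 limma fits were chosen after the data had been seen. Of 264 alternatives to the comparisons, 214 kept direction and side of the threshold (8 reversed), as did 245 of 269 with 1 library left out (5 reversed) and 225 of 254 for single pre-miRNAs (29 lost the call, 0 reversed). Except where stated, the cause was not tested. The edgeR alternative was not run.

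Weighted by reads, intact ends gave −6.73 (dcl1-7), −11.7 (se-1) and 7.01 (hyl1-2). Tailed shares gave 7.14 (dcl1-7), −1.09 (se-1), 10.8 (hyl1-2), 9.56 (ago1-36) and 11.9 (hen1-8). C tails in heso1-1 gave 2.79, U tails in heso1-2 −2.89, and the genotype spreads 1.06 (U) and 2.68 (C). By the median over pre-miRNAs, C in heso1-1 was 0.205, U in heso1-2 −4.83 and tailed hen1-8 0.0498. Tails of at least 2 nt gave −0.431 (C, heso1-1, passing), −0.637 (U, heso1-2), 0.632 (tailed, hen1-8) and a U spread of 0.179. A minimum of 10 reads gave −5.004 for heso1-2. One of 200 gave 0.435 for tailed hen1-8 and spreads of 1.33 (U) and 2.56 (C). Untailed reads alone gave −5.08 for hyl1-2, not passing. Replicates 4 and 5 alone gave −5.64 for U in heso1-1 (exact p = 0.333, the smallest for 2 against 2). Within sets the C spread was 2.43.

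Counts that moved by over 1.5 times were these. With at least 200 reads, which leaves fewer to test: 12 (dcl1-7), 12 (se-1), 6 (hyl1-2), 1 (C, double) and 1 (C, triple). With depth weights: 16 (C, heso1-1), 14 (se-1), 2 and 3 (U, double and triple), 4 and 11 (C, double and triple). At the annotated end: 11 (se-1) and 4 (hyl1-2). With next base A or G, which leaves fewer: 13 (U) and 2 (C) in heso1-1. Tails of at least 2 nt: 19 (U, heso1-1) and 1 (C, double). A fit on 2 groups: 4 (C, heso1-1) and 4 (U, ago1-36). Negatively signed reads: 4 (C, double). The set-letter block: 12 and 13 (C, double and triple).

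Replicate numbers pair only ago1-36 (3 of 3 best with their own number), where the block gave 5.42. Elsewhere the libraries share only a number (U in heso1-1, correlations −0.174 to 0.491). With the replicate block U in heso1-1 stayed at −6.91 (exact p = 0.0312) and counts were 52 (U) and 8 (C) in heso1-1, 21 (dcl1-7), 28 (se-1), 15 (hyl1-2), 19 (transgene), 13 (ago1-36), and 1 each for C in the double and triple mutants.

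Leaving out 1 library gave −8.60 to −6.54 (U, heso1-1), −1.30 to 0.288 (C, heso1-1; 0.288 without Col-0 replicate 4), 2.72 to 3.76 (transgene; exact p = 0.143 without either of its libraries, the smallest left) and −6.94 to −6.67 (heso1-2). Intact ends gave −11.5 to −8.77 (dcl1-7), −14.8 to −11.9 (se-1) and −8.92 to −6.79 (hyl1-2). Tailed shares gave 1.70 to 3.20 (dcl1-7), 0.396 to 3.01 (se-1), 2.30 to 5.07 (hyl1-2), 3.44 to 5.06 (ago1-36) and −0.681 to 0.711 (hen1-8). Spreads were 1.55 to 1.99 (U) and 2.13 to 2.67 (C), and restored length 3.94 to 4.69 (exact p = 0.0625, the smallest for 5). Counts were 45 to 51 (U) and 3 to 9 (C; 3 without heso1-1 replicate 1, 4 without replicate 2 or Col-0 replicate 4) in heso1-1, 16 to 27 (dcl1-7), 18 to 28 (se-1), 6 to 17 (hyl1-2; 6, 7 and 8 without replicate 2, replicate 3 or Col-0 replicate 1), 0 to 0 (U, double and triple), 0 to 0 (C, double), 0 to 1 (C, triple), 12 to 21 (transgene; 12 without its replicate 2) and 4 to 14 (ago1-36; 4 without its replicate 2). Depth limits the small classes: 19 pre-miRNAs reached 50 reads in every library.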

Other observations

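The limma test of ago1-36, the tests by last templated base and those at the annotated end and at the commonest end of all reads were chosen only after results had been seen, and the tests by position of the end lay outside the design.

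In ago1-36 more tailed reads held U than C when reads were pooled over pre-miRNAs. Of tailed reads 64.3% ± 3.29 held only U and 25.9% ± 3.56 only C (SD, n = 3), against 36.1% and 52.8% in Col-0. The mean U-tail share was 14.3% ± 1.03 against 11.2% ± 1.00, with 3 of 3 libraries above every Col-0 library (exact permutation p = 0.0119, adjusted p = 0.0853 over 43 tests, which does not pass). All ago1-36 libraries were read in lane 5, where no Col-0 library with a lane given was read. Over the 19 pre-miRNAs common to all libraries they had 13.6 to 15.8% U tails. Lane 5 libraries of other genotypes without a heso1 allele had 6.68% (ntp5-1 replicate 1) to 14.5% (soe2), so lane stays open. The mean C-tail share was 12.6% ± 1.70 against 12.9% ± 2.95 (exact permutation p = 0.869 with n = 3 and 6, adjusted p = 0.958). In limma U tails rose in 11 pre-miRNAs and fell in 4 of 52 (18 at an unadjusted p under 0.05), and C tails fell in 4 and rose in 2 of 52 (10 at an unadjusted p under 0.05). U tails rose in MIR169m (19.7 to 42.5%, log2 1.61), MIR165a (20.04 to 39.4%, 1.37), MIR166b (11.1 to 26.9%, 1.73), MIR166a (10.8 to 20.2%, 1.10) and MIR164c (38.6 to 59.2%, 1.26). They fell in MIR393a (14.9 to 1.81%, −3.26), MIR822 (−3.04), MIR169d (−1.64) and MIR160c (21.2 to 11.3%, −1.10). C tails of MIR169m, named after its values were seen, fell from 14.1 to 4% (limma, −1.95). Since same-numbered libraries deviated together, the 15 calls for U tails were set against the 8 splits that take 1 library of each pair, which are too few for a share under 0.05 (highest other 1). The other splits leave pairs together. A fit on both groups alone gave 4 calls, as did leaving out ago1-36 replicate 2.

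Several single-library genotypes had few C tails. mac-7, a mutant of a spliceosome-associated complex, had 5.25% against 13.3% in Col-0 (51 pre-miRNAs), and ago1-27 had 6.58% against 13.6% (49 pre-miRNAs). Pooled over reads, the shares were 9.28% (Wilson 9.23 to 9.34%) and 8.00% (Wilson 7.92 to 8.08%), against lowest Col-0 values of 10.5%. Both libraries lay at extremes of the series. mac-7 had the most pre-miRNA reads (982385) and the smallest share kept with 1 mismatch (0.75%). ago1-27 had the smallest share of products with too little templated sequence (68.4%, median 95.8%). Whether these library differences bear on the C tails was not tested. Ler had more A tails than Col-0, 2.61% ± 0.866 against 0.641% ± 0.0641 over 28 pre-miRNAs (exact permutation p = 0.0119 with n = 3 and 6, adjusted p = 0.0853). Ler reads were compared with the Columbia sequence.

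The first hypothesis was that U tails sit more often on trimmed than on intact ends, and it stays undecided. Over ends not followed by U in the template, U tails were on 21.5% of Col-0 reads ending upstream and on 10.0% at the intact end, a difference of 11.5 percentage points. The intact end was chosen for holding the most untailed reads, which favours a low share of tails there. With the commonest end of all reads, tailed or not, the difference was 8.92 (6 of 6 libraries, exact sign-flip p = 0.0312), but that end was the same in 91 of 101 pre-miRNAs. At the annotated end it was −0.0324 (positive in 3 of 6, exact sign-flip p = 1).

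The second hypothesis was that C tails sit more often on intact ends. The Col-0 difference was opposite with each reference end: 13.1 percentage points at the commonest untailed end, where the same limit holds, 9.13 at the commonest end of all reads and 17.4 at the annotated end (6 of 6 libraries each, exact sign-flip p = 0.0312). The annotated end left only 3 to 12 pre-miRNAs per library.

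Median shares over the Col-0 pre-miRNAs prompted another pair of hypotheses. C tails had a median of 19.9% where the last templated base was U and 9.51% where it was C, and U tails 8.33% after C and 3.13% after U. Within pre-miRNAs C tails were on 8.00% of Col-0 ends after U and on 29.2% after C, a difference of −21.2 percentage points, negative in 6 of 6 libraries (exact sign-flip p = 0.0312). This is opposite to the hypothesis. In heso1-1 the difference was −31.0. For U tails the difference was −2.46 (exact sign-flip p = 0.281, n = 6), which left the hypothesis undecided. A tail of several C on the end before a templated C reads as a shorter C tail after it, and its share in these values was not tested.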
